A study of Mus musculus with 4 samples.

How the data were processed

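CT26 is a colon carcinoma cell line from Balb/c mice that grows as a tumour when implanted. Per the labels, 2 libraries came from control tumour-bearing mice and 2 from mice given liproxstatin-1, an inhibitor of ferroptosis (cell death driven by iron and lipid peroxides), for 8 days. The mice were 9 weeks old. Cells of dissociated tumours were positively selected with magnetic beads against CD45, a surface protein of leukocytes, and libraries were prepared by a 10x Genomics droplet protocol that reads the 3' end of transcripts, per the labels' protocols. The labels give replicate numbers, and nothing in them says whether the 2 replicates of a group are separate animals. The p-values of genes and shares therefore measure only the spread between these libraries, which may be technical. The numbers in the file names differ from those of the labels except for control replicate 1, and would give control replicate 1 and liproxstatin replicate 2 the same number. The labels' numbers are used throughout, also for the replicate block and for leaving out libraries. What the control mice received in place of the drug, and the day or batch of each library, are not given in the sources used here.

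The deposited values are counts: whole numbers of unique molecular identifiers (UMIs) per gene and barcode, not normalized, 1 matrix per library, per the file headers. The matrix headers name Cell Ranger 6.1.1, whereas the submitters' processing notes name Cell Ranger 4 and the mouse build mm10. The difference in version stays unresolved. The matrices list 32285 genes and 29092 barcodes, and every barcode in them has at least 500 UMIs. Total UMIs per library ran from 83129874 to 168597163. Gene positions were read from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, in which 32158 of the 32285 gene identifiers were found.

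Cells with at least 200 detected genes and under 15% mitochondrial UMIs were kept. Scrublet scores, computed per library with scanpy 1.11.5, ranked the cells by resemblance to simulated doublets. The highest-scoring cells were called doublets, stayed in for the clustering and were left out of every comparison, at a rate of 0.8% per 1000 barcodes, which took 3.30% to 7.44% of the cells of a library. Scrublet's own threshold would have called between 5 and 212 cells per library. This left 25730 cells.

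Counts were scaled per cell and log-transformed, 2682 of 3000 variable genes were used after Xist, Gm-numbered, ribosomal, mitochondrial, haemoglobin and antigen-receptor segment genes were left out, and 40 principal components entered a shared-neighbour graph of 20 nearest neighbours. Leiden clustering at resolution 1 (python-igraph 0.11.9) gave 32 clusters. No batch integration was used. Each cluster took the name of the marker list, out of 23 lists fixed before the data were examined, with the highest mean standardised expression. CD8, regulatory and other T cells were parted by the share of cells with Cd8a, Cd4 and Foxp3. A name therefore means only that a cluster was like that cell type by these markers, and plain names such as neutrophils are used for neutrophil-like clusters throughout. The numeric naming thresholds were set after the clusters had been seen. So was the exception by which markers of a sister class of the same family (T cells, phagocytes or dendritic cells) did not count against a name. 7 clusters stayed unnamed for low marker scores, too few detected markers, low UMI counts, mostly doublets, or more markers of another class. They held 20.5% and 10.0% of the immune cells of control replicates 1 and 2, and 9.37% and 3.95% of those of liproxstatin replicates 1 and 2. The largest of them had a median of 1315 UMIs per cell and was led by AY036118, Gm42418 and Lars2. An unnamed neutrophil-like cluster, over 50% of whose cells scored as doublets, held 0.161% and 0.372% of control and 0.131% and 0.113% of liproxstatin immune cells. Conventional CD4 T cells could not be parted from other T cells by cluster and were not tested as a class.

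Counts were summed per library and class, for classes with at least 20 cells in every library. Each class was fitted alone with edgeR 4.0.16 under R 4.3.3. The steps were filterByExpr, TMM normalization, robust dispersions and the quasi-likelihood F test of treatment, with Benjamini-Hochberg adjustment over the genes of the class and a threshold of 0.05. Log2 fold changes are liproxstatin over control, with n = 2 libraries per group. Their standard errors (SE) are the log2 fold change divided by the square root of F. Levels are CPM, the UMIs of a gene scaled to a fixed total of the class. Shares were tested by edgeR quasi-likelihood on cell numbers with the immune cells of the library as offset, and by an exact permutation test, for which 2 against 2 libraries give no two-sided p below 0.3333. The difference in response between neutrophils and mononuclear phagocytes was an edgeR quasi-likelihood interaction term with the library as a block.

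22 gene lists were fixed before the data were examined. They cover ferroptosis-promoting genes, ferroptosis defence, eicosanoid synthesis, lipid uptake, myeloid suppression, MHC class II and class I presentation, type I interferon and interferon gamma responses, NF-kappaB and cytokines, hypoxia and glycolysis, integrated stress, oxidative phosphorylation, cell cycle, cytotoxic effectors, T cell exhaustion, naive and memory T cells, T cell receptor activation, regulatory T function, lymphocyte chemokines, neutrophil granules, and dissociation stress. Limma 3.58.1 camera tested each list with at least 5 measured genes against the other genes of the class, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 174 tests. Camera with an estimated correlation and fry were the alternatives. With the preset, camera p-values rest on the spread across genes at that assumed correlation. Very small ones therefore do not measure how well the libraries repeat.

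Named genes followed a rule fixed before the data were examined. For each class it took up to 10 genes with the largest called change in each direction whose libraries did not overlap between the groups, leaving out predicted, mitochondrial, ribosomal and antigen-receptor genes. A fixed panel was given whether or not its genes passed, and up to 4 called members were taken per gene list, by smallest p. Genes with close paralogs can share UMIs with their copies, so Gbp5, Gzmg, Rnase2a, Ifi206, Ifit3b, Klra7 and the Hist1 genes are reported as uncertain. Some genes that the rule takes are not reported here.

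RNA released by broken cells gives UMIs in droplets of other cells. C1qa, a macrophage gene, had a UMI in 98.6% of macrophages (median 29198 UMIs per cell), and also in 58.4% of CD8 T cells (median 12864 UMIs) and 45.6% of neutrophils (median 3304 UMIs). The level of the C1q genes set how much free phagocyte RNA a class could hold, from 1.34% of the phagocyte level in CD8 T cells to 4.20% in neutrophils and 19.4% in B cells. Genes of which this could give over 50% of the UMIs are called prone to free RNA below.

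The tests were checked on simulated counts with 200 changed genes per class. With gene-wise spreads taken from the real fits, changes of 4-fold were recovered for 88% (neutrophils and NK cells) to 96% (pooled T cells) of the changed genes outside B cells, and for 26% in B cells. Changes of 2-fold were recovered for 41% in neutrophils, 45% in regulatory T cells, 77% in mononuclear phagocytes and 1% in B cells. Between 6.52% (neutrophils) and 21.0% (mononuclear phagocytes) of these calls were false, above the nominal 5%, and data with no change gave 3 to 19 calls per class. A simulation with the smoothed trend of the spread was added after that result. It gave 3.10 to 8.99% false calls and 0 calls with no change, and recovered 44% of changes of 4-fold in B cells and 78% (neutrophils) to 97% (pooled T cells) elsewhere. The interaction test, simulated on the 5824 genes shared by both classes, recovered 194 of 200 genes changed 4-fold, with 28 false calls. Camera recovered the 1 raised list with the preset correlation and did not with an estimated one. The simulated genes varied independently of one another, a setting that favours the preset, and fry was not simulated.

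Alternatives fixed in advance were size factors of the DESeq2 kind (edgeR RLE), no filter on low counts, the DESeq2 1.42.0 Wald test, the replicate number as a block, leaving out each library, doublets kept, at least 500 genes per cell, under 10% mitochondrial UMIs, resolutions 0.5 and 2, equal numbers of cells per library, and all classes in 1 fit. For shares the denominator and TMM scaling were also varied. After the data had been seen, fits of monocytes and macrophages alone, equal cells per cluster, without genes prone to free RNA, and with named clusters as denominator were added. Figures were drawn with matplotlib 3.10.9.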

Results

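CD45-selected cells of CT26 tumours were compared between control mice and mice given liproxstatin-1 for 8 days, with 2 libraries per group. The series title concerns ferroptosis of tumour neutrophils, so the comparison asks how the leukocytes of the tumour, neutrophils first, differ when ferroptosis is inhibited. The libraries of control replicates 1 and 2 held 4138 and 6996 barcodes with 83129874 and 162158147 UMIs. Those of liproxstatin replicates 1 and 2 held 8659 and 9299 barcodes with 168597163 and 165165389 UMIs. Kept cells had median UMI counts of 16817, 19462, 16405 and 15421 in the same order. Control replicate 1 had the fewest UMIs in total and the fewest cells, 3753 of the 25730 kept.

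Macrophages and monocytes were the largest named classes in both groups. Macrophage-like cells were 37.2% ± 5.97 (SD, n = 2) of immune cells in control and 37.5% ± 2.75 in liproxstatin tumours, and monocyte-like cells 14.9% ± 1.97 and 19.3% ± 1.56. CD8 T cells were 8.86% ± 2.79 and 12.1% ± 0.739, NK cells 6.72% ± 1.45 and 6.44% ± 0.350, and regulatory T cells 1.72% ± 0.188 and 2.55% ± 0.308. Neutrophil-like cells were 4.88% ± 3.19 and 6.28% ± 1.92, with 98 and 442 cells in the control libraries and 583 and 393 in the liproxstatin libraries. Short names without "-like" are used from here on. B cells were 0.626% ± 0.0516 and 0.415% ± 0.0864, and conventional dendritic cells of type 1 were 1.68% and 1.44% on average. No class share differed by edgeR quasi-likelihood with Benjamini-Hochberg adjustment (0 of 14, lowest adjusted p = 0.915). 0 classes had an unadjusted p under 0.05, the lowest being 0.13 for regulatory T cells, and the lowest exact permutation p, two-sided, was 0.3333, the smallest that 2 against 2 libraries allow. The unnamed clusters held 20.5% and 10.0% of the control and 9.37% and 3.95% of the liproxstatin immune cells, so shares of named classes also carry that difference.

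**Figure D1:**
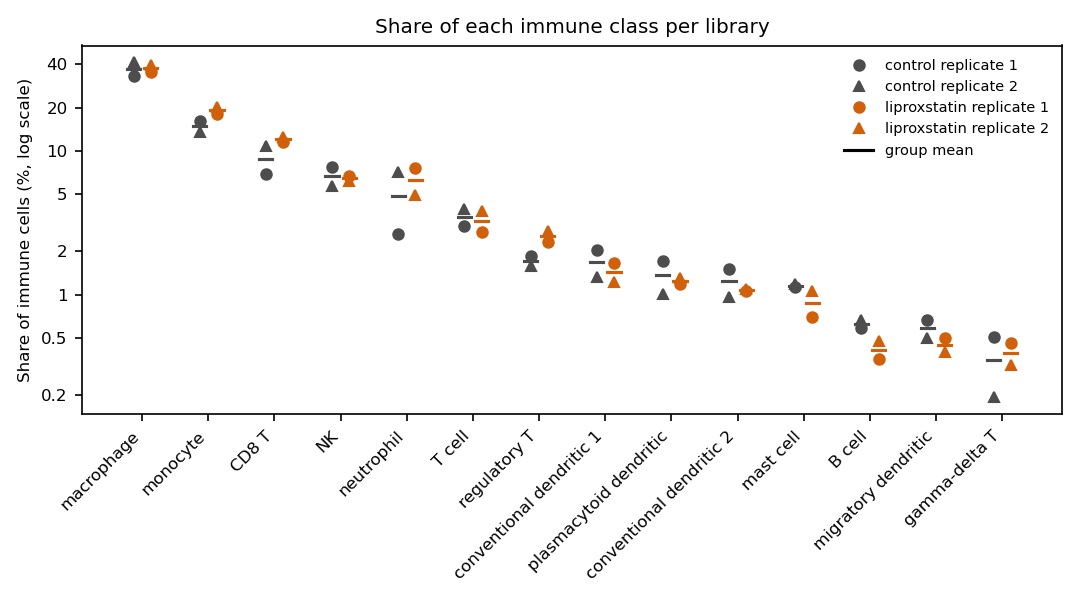
Share of immune cells (percent, logarithmic vertical axis) for each of 14 named classes (horizontal axis), with 1 point per library, grey for control and orange for liproxstatin, and lines for group means. Neutrophils lay at 2.63% and 7.14% in control and at 7.64% and 4.92% in liproxstatin tumours.

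Neutrophils of liproxstatin-treated tumours had higher RNA levels of Icam1, Cxcl10 and Tsc22d3. Icam1, an adhesion molecule (ENSMUSG00000037405, chromosome 9, 21015985 to 21028817, plus strand, GRCm38), rose by a log2 fold change of 1.93 ± 0.30 (SE, n = 2 per group), from 34.9 and 20.8 CPM in control to 83.3 and 104 CPM. Cxcl10, a chemokine for CXCR3-bearing lymphocytes (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, minus strand), rose by 1.55 ± 0.24, from 84.4 and 92.0 CPM to 225 and 299 CPM. Tsc22d3, the glucocorticoid-induced leucine zipper gene (ENSMUSG00000031431, chromosome X, 140539528 to 140600659, minus strand), rose by 1.37 ± 0.23. Their adjusted p were 0.0055, 0.0055 and 0.0099 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Among the other genes that rose were Rdh11 (2.11 ± 0.42), Gbp5 (1.60 ± 0.27, uncertain because of its paralogs), Crispld2 (1.45 ± 0.30), Klf3 (1.24 ± 0.23) and Rdh12 (1.12 ± 0.21). Efr3b (-3.28 ± 0.59), Fam71f2 (-2.27 ± 0.33), the adhesion gene Pecam1 (-2.02 ± 0.41), B4galt5 (-1.80 ± 0.35) and Arfgef2 (-1.33 ± 0.26) fell. In all, 9 genes rose and 7 fell of 5857 tested, with 478 at an unadjusted p under 0.05, and the libraries of the groups did not overlap for 35.6% of the tested genes, where chance gives 33.3%. With all classes in 1 fit 130 rose and 19 fell, with equal numbers of cells per library 0 genes passed, Icam1 then at 1.39 (adjusted p = 0.64, edgeR), and without liproxstatin replicate 2 Cxcl10 did not pass at 1.36 (adjusted p = 0.11, edgeR), nor did Tsc22d3 at 1.33 (adjusted p = 0.15). Simulated data without any change gave 5 calls in this class with gene-wise spreads and 0 with the smoothed trend, and the count was 296 without control replicate 1, 64 without control replicate 2, 9 without liproxstatin replicate 1 and 7 without liproxstatin replicate 2.

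None of the fixed panel genes tied to ferroptosis and given here passed the test in neutrophils. Gpx4, the phospholipid peroxidase whose loss permits ferroptosis, had a log2 fold change of -0.09 ± 0.23 (SE, n = 2 per group), Slc7a11 -0.18 ± 0.23, Acsl4 0.23 ± 0.34, Ptgs2 -0.25 ± 0.24, Tfrc 0.30 ± 0.42 and Hmox1 -0.10 ± 0.24. The checkpoint ligand gene Cd274 was at -0.10 ± 0.23 and Il1b at -0.05 ± 0.25. Of the ferroptosis-promoting list 18 members were measured with a median of -0.04 (limma camera adjusted p = 0.654), and of the ferroptosis defence list 17 with a median of 0.05 (adjusted p = 0.933). For both, the test pointed upward and the mean lay just below 0. The interferon gamma list was higher, with a median of 0.41 over 22 members (camera adjusted p = 7.31e-07, and adjusted p = 0.682 with an estimated correlation). Of its members 2 rose over all genes, and 5 rose and 0 fell when adjusted over the list alone. The NF-kappaB list was higher (median 0.16, 26 members, 1 rose, 3 up and 1 down adjusted over the list alone; camera adjusted p = 0.0241, and adjusted p = 0.685 with an estimated correlation). Lower lists were MHC class II (median -0.50, 12 members of which 6 were prone to free RNA, adjusted p = 0.0282), hypoxia (-0.27, adjusted p = 0.0119), integrated stress (-0.28, adjusted p = 0.0114) and oxidative phosphorylation (-0.13, adjusted p = 0.0319), all by limma camera. With an estimated correlation these 4 had adjusted p = 0.72, 0.747, 0.682 and 0.682. No member of the 4 fell over all genes, and adjusted over the list alone 3 MHC class II members and 1 oxidative phosphorylation member fell. Without control replicate 2 the MHC class II, NF-kappaB and hypoxia lists turned direction (camera adjusted p = 0.438, 0.681 and 0.488).

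**Figure D2:**
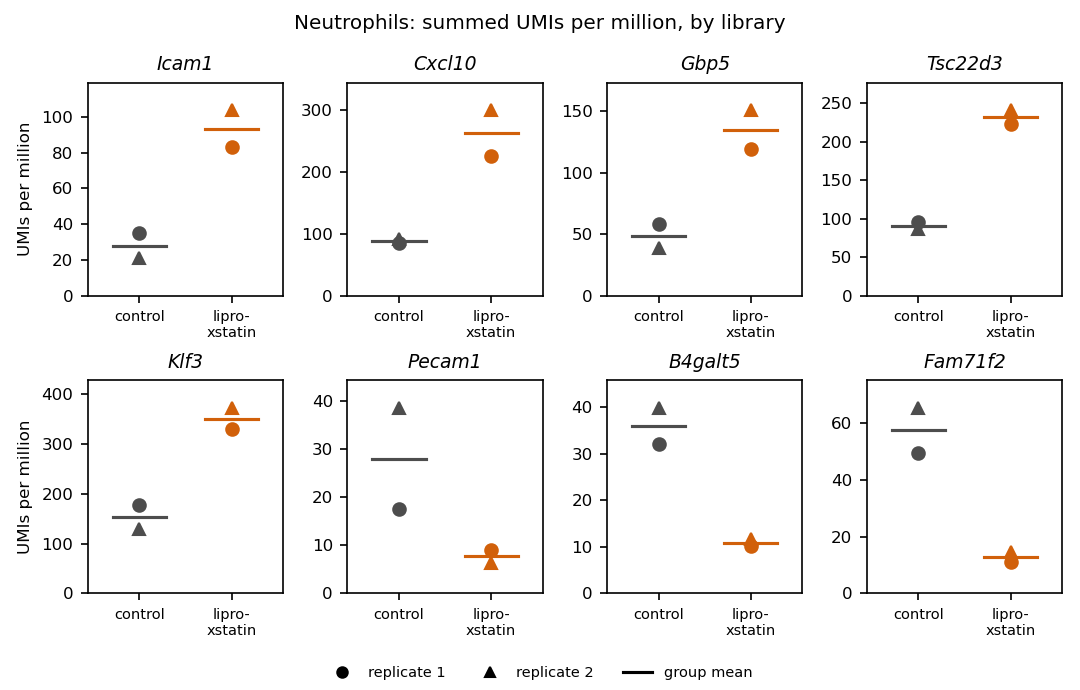
Levels of 8 genes in neutrophils (CPM, linear vertical axis from 0, 1 panel per gene) in control and liproxstatin tumours, with 1 point per library, circles for replicate 1, triangles for replicate 2 and lines for group means. Icam1 lay at 34.9 and 20.8 CPM in control and at 83.3 and 104 CPM in liproxstatin tumours.

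Monocytes and macrophages, pooled as mononuclear phagocytes, had higher RNA levels of Ifnb1, Slc7a11 and Tsc22d3. Ifnb1, the gene of interferon beta (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774, minus strand), rose by a log2 fold change of 4.37 ± 0.45 (SE, n = 2 per group) from very low levels, 0.126 and 0.0268 CPM in control against 1.30 and 1.31 CPM. Tsc22d3 (1.22 ± 0.09), Klf9 (1.46 ± 0.12) and Per1 (1.58 ± 0.17; ENSMUSG00000020893, chromosome 11, 69095217 to 69109960, plus strand) rose. Slc7a11, the cystine transporter that supplies glutathione synthesis (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614, minus strand), rose by 0.98 ± 0.14, and the costimulatory ligands Cd80 and Cd86 by 0.88 ± 0.12 and 0.54 ± 0.09. Tgfb3 (1.25 ± 0.11), Cd38 (0.81 ± 0.08), Havcr2 (0.77 ± 0.11), Nt5e (0.70 ± 0.09) and Pdcd1lg2 (0.57 ± 0.12) rose, whereas Lix1 (-1.84 ± 0.23), Dbp (-1.01 ± 0.15), Ednrb (-0.97 ± 0.13) and Hpgds (-0.47 ± 0.08) fell. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment the adjusted p was 0.0027 for Ifnb1, 0.000375 for Tsc22d3, 0.0012 for Klf9, 0.0163 for Per1 and 0.025 for Slc7a11. Of 14608 genes tested 164 rose and 123 fell, with 2363 at an unadjusted p under 0.05. Libraries did not overlap for 49.2% of the genes, where chance gives 33.3%. Median UMIs per cell of this class were 27854 and 29687 in control and 24382.5 and 20514 in liproxstatin libraries. Whether this difference in depth bears on the calls was not tested. The genes higher and lower numbered 650 and 379 without control replicate 1, 333 and 348 without control replicate 2, 21 and 29 without liproxstatin replicate 1 and 40 and 4 without liproxstatin replicate 2, where in the last 2 settings Ifnb1 did not pass (edgeR adjusted p = 0.071 and 0.072), and 74 and 14 with equal cells per cluster, a setting added after the data had been seen. Slc7a11 was at 1.1 in macrophages alone (adjusted p = 0.0964, edgeR) and at 0.55 in monocytes alone (adjusted p = 0.61).

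Mucl1 fell in mononuclear phagocytes from 328 UMIs over the control libraries, 322 of them in monocytes, to 7 over the liproxstatin libraries, 58.9-fold lower in CPM. With doublets kept its log2 fold change was -0.30 and did not pass (edgeR adjusted p = 0.96), nor did it pass at resolution 0.5 (adjusted p = 0.14). The panel genes Cd274 (0.39 ± 0.09, edgeR adjusted p = 0.0564), H2-Ab1 (0.46 ± 0.17), Vegfa (0.86 ± 0.17), Cxcl9 (0.40 ± 0.22), Ptgs2 (0.85 ± 0.84), Il1b (0.58 ± 0.70), Arg1 (-0.05 ± 0.38) and Gpx4 (-0.07 ± 0.10) did not pass (n = 2 per group).

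Cell cycle genes were lower in mononuclear phagocytes of liproxstatin-treated tumours. The list had a median log2 fold change of -0.32 over 36 members, of which 16 fell, such as Tk1 (-0.56 ± 0.08), Plk1 (-0.60 ± 0.09), Aurka (-0.61 ± 0.09) and Aurkb (-0.56 ± 0.08), and 25 fell when adjusted over the list alone (camera adjusted p = 7.82e-27, and adjusted p = 0.682 with an estimated correlation). With equal cells per cluster the median was -0.05 and 0 members fell. The dissociation list was higher (median 0.42, 21 members, of which Dusp1, Fosb and Dnajb1 rose; 8 rose adjusted over the list alone), as was the list of T cell exhaustion genes (median 0.37, 20 members, of which Cd38, Rgs1 and Havcr2 rose; 6 adjusted over the list alone). Their camera adjusted p were 1.76e-10 and 4.2e-07, and both had adjusted p = 0.682 with an estimated correlation. MHC class II and costimulation was higher (0.38, 17 members, Cd80 and Cd86 rose, 4 adjusted over the list alone, adjusted p = 7.18e-05), as were NF-kappaB (0.52, 0 of 28 rose, adjusted p = 0.000171) and interferon gamma (0.14, 0 of 28 rose, 1 adjusted over the list alone, adjusted p = 0.0017), by limma camera. Ferroptosis defence was higher with Slc7a11 as the 1 of 24 members that rose (median 0.11, camera adjusted p = 0.0241). With an estimated correlation these 4 had adjusted p = 0.685, 0.705, 0.716 and 0.682. Other lists called upward were hypoxia (0.07, P4ha1 rose), lipid uptake (0.13), myeloid suppression (0.08, Havcr2 and Pdcd1lg2 rose), neutrophil granules (0.32) and T cell receptor activation (0.35), and oxidative phosphorylation was lower (-0.13). None of these held with an estimated correlation, with which the 65 calls over all classes had adjusted p between 0.682 and 0.775. Hypoxia turned direction without control replicate 1 (camera adjusted p = 0.645).

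The responses of neutrophils and mononuclear phagocytes were compared directly. Thbs1, the gene of thrombospondin 1, had a log2 fold change of -1.19 in neutrophils and 0.78 in mononuclear phagocytes, a difference of -2.01 ± 0.23 (SE, n = 2 per group), and the nuclear receptor gene Nr4a2 differed by -3.57 ± 0.45. Ptgs2 (-1.21 ± 0.23), Slc7a11 (-1.02 ± 0.23), Vegfa (-1.14 ± 0.26) and the MHC class II gene H2-Ab1 (-1.01 ± 0.26), of whose UMIs in neutrophils free RNA could give 44.0%, also had a lower log2 fold change in neutrophils. Icam1 (1.81 ± 0.30) and Cxcl10 (1.41 ± 0.25) had a higher one. The 13546 genes tested passed a filter over both classes together, against 5857 in neutrophils alone. Mgl2 and Lztfl1, called downward, did not pass the filter in neutrophils alone. No interaction fit left out genes prone to free RNA. Whether free RNA bears on the genes called downward, the MHC class II genes H2-Eb1 (-1.38) and H2-Aa (-1.32) among them, was not tested. The interaction term was called for 48 genes of 13546, 9 upward and 39 downward, by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, with 748 at an unadjusted p under 0.05. The count was 193 without control replicate 1, 3 without liproxstatin replicate 1 and 2 without liproxstatin replicate 2, and Icam1, Cxcl10, Slc7a11, Vegfa and H2-Ab1 passed in neither of the last 2 settings. Without control replicate 2 Icam1 (1.51, edgeR adjusted p = 0.0905), Vegfa (-0.14, adjusted p = 1.0) and H2-Ab1 (0.16, adjusted p = 1.0) did not pass.

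Dendritic cells of liproxstatin-treated tumours had higher Tsc22d3 (log2 fold change 1.53 ± 0.13, SE, n = 2 per group), Enc1 (1.51 ± 0.26), Zfp36l2 (0.95 ± 0.13), Ddit4 (0.84 ± 0.13) and the metallothionein Mt1 (0.84 ± 0.12). Timp1, an inhibitor of metalloproteinases (-1.36 ± 0.16), the interferon-induced gene Ifit3b (-1.35 ± 0.22, uncertain because of its paralogs) and Mfge8 (-1.25 ± 0.23) fell. Adjusted p were 0.000236 for Tsc22d3 and 0.0022 for Timp1 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, and 12 genes rose and 3 fell of 10542, with 863 at an unadjusted p under 0.05. The type I interferon list was lower (median -0.27, 29 members, Ifit3b fell, 2 adjusted over the list alone; camera adjusted p = 1.69e-05, and adjusted p = 0.705 with an estimated correlation) and turned direction without control replicate 1 (camera adjusted p = 0.291). The dissociation list was higher (0.46, 21 members, 4 adjusted over the list alone; camera adjusted p = 1.03e-08, and adjusted p = 0.682 with an estimated correlation). Oxidative phosphorylation (-0.12) and regulatory T function (-0.33) were lower, both with adjusted p = 0.685 with an estimated correlation. Data simulated without change gave 10 calls here with gene-wise spreads and 0 with the smoothed trend. The genes higher and lower numbered 221 and 96 without control replicate 1, 89 and 133 without control replicate 2, 3 and 2 without liproxstatin replicate 1, 3 and 0 without liproxstatin replicate 2, and 7 and 9 with equal cells per library.

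CD8 T cells had higher RNA levels of Il7r, Slamf6 and Zfp36l2. Il7r, the receptor chain for interleukin 7 (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176, minus strand), rose by a log2 fold change of 0.99 ± 0.12 (SE, n = 2 per group), Slamf6 by 1.40 ± 0.19, and Zfp36l2 (ENSMUSG00000045817, chromosome 17, 84183931 to 84187947, minus strand) by 2.38 ± 0.24. Tsc22d3 rose by 1.89 ± 0.12, the small heat shock gene Hspb1 by 2.86 ± 0.41, Cd28 by 0.83 ± 0.14, Ccl5 by 0.81 ± 0.10, Tigit by 0.78 ± 0.19 and Cx3cr1 by 0.76 ± 0.13. Gzmg fell (-3.56 ± 0.36, uncertain because of its paralogs) and did not pass with doublets kept (edgeR adjusted p = 0.53). Adjusted p were 5.11e-05 for Il7r, 0.000251 for Slamf6, 0.0319 for Zfp36l2 and 2.14e-10 for Tsc22d3 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. The effector and exhaustion genes Ifng (-0.11 ± 0.11), Gzmb (-0.11 ± 0.13), Pdcd1 (0.31 ± 0.14), Havcr2 (0.37 ± 0.13), Lag3 (-0.03 ± 0.11), Tox (0.02 ± 0.12) and Tcf7 (0.41 ± 0.20) did not pass. At resolution 2 a CD8 T cell cluster led by Ccr7 and Dapl1 held 34 and 108 control and 207 and 246 liproxstatin cells. The largest CD8 T cell cluster there held 176 and 440 control and 550 and 593 liproxstatin cells. Whether this mix of clusters sets the rises of Il7r, Slamf6 and Zfp36l2 was not tested. Equal cells per cluster used the clusters of resolution 1, where no such cluster was parted. Of 11656 genes 92 rose and 37 fell, with 1227 at an unadjusted p under 0.05. The count was 453 without control replicate 1, 169 without control replicate 2, 25 without liproxstatin replicate 1 and 33 without liproxstatin replicate 2, and 17 with equal cells per library.

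By list, naive and memory T cell genes were higher in CD8 T cells (median 0.32, 15 members, of which 2 rose, Il7r and Slamf6, and 1 fell, also when adjusted over the list alone), with camera adjusted p = 0.000278. Exhaustion genes were higher (0.22, 22 members, Tigit rose, 4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0022), as was T cell receptor activation (0.17, 19 members, Cd28 and Tnfrsf4 rose, 3 adjusted over the list alone, camera adjusted p = 0.0073). These 3 lists had adjusted p = 0.682 with an estimated correlation. The cytotoxic list was not called (camera adjusted p = 0.563), with the test upward and the median (-0.09) and mean (-0.19) below 0, though its members Ccl5 and Cx3cr1 rose. MHC class II genes were lower (median -0.36, 15 members, 3 fell, 1 up and 5 down adjusted over the list alone; camera adjusted p = 0.000171, and adjusted p = 0.682 with an estimated correlation), with H2-Ab1 at -0.53 ± 0.12 and H2-Eb1 at -0.69 ± 0.16. Of these 15 members 8 were prone to free RNA, as were 5 of the genes that fell in the class, Lgmn, Ccl8 and Fcgr2b among them. Type I interferon (-0.27), oxidative phosphorylation (-0.20), MHC class I (-0.08) and cell cycle (-0.11) were lower and regulatory T function (0.21) and dissociation (0.26) higher by camera, and none held with an estimated correlation (adjusted p between 0.682 and 0.775).

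Regulatory T cells, with 69 and 98 control and 178 and 221 liproxstatin cells, had higher Zfp36l2 (2.20 ± 0.14, SE, n = 2 per group), Sgip1 (2.84 ± 0.37), Cenpf (2.97 ± 0.66), the integrin gene Itgav (1.47 ± 0.20), Tsc22d3 (1.34 ± 0.17), Il7r (1.08 ± 0.15) and Icos (0.63 ± 0.14). Ltb4r1 (-2.02 ± 0.34), Zfp36 (-1.32 ± 0.17), Klrg1 (-0.99 ± 0.18) and S100a4 (-0.66 ± 0.12) fell. Foxp3 (-0.02 ± 0.15), Ctla4 (0.65 ± 0.15) and Gzmb (-0.47 ± 0.13) did not pass. Adjusted p were 1.81e-14 for Zfp36l2 and 7.66e-06 for Sgip1 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, and 18 genes rose and 6 fell of 7258, with 559 at an unadjusted p under 0.05. Those higher and lower numbered 53 and 11 without control replicate 1, 28 and 33 without control replicate 2, 15 and 8 without liproxstatin replicate 1 and 28 and 8 without liproxstatin replicate 2, and 6 and 3 with equal cells per library. Cell cycle genes were higher (median 0.41, 19 members, Cenpf rose, 5 adjusted over the list alone, camera adjusted p = 6.09e-05) and cytotoxic genes lower (-0.46, 16 members, Klrg1 fell, 2 adjusted over the list alone, camera adjusted p = 7.18e-05), both with adjusted p = 0.682 with an estimated correlation. Regulatory T function was not called (camera adjusted p = 0.899). Pooled T cells, which contain the CD8 and regulatory T cells, had higher Il5 (2.82 ± 0.44), Ccr6 (1.75 ± 0.35), Tsc22d3 (1.69 ± 0.11), Klf9 (1.41 ± 0.21) and Dusp1 (1.13 ± 0.12) and lower Egr3 (-0.97 ± 0.21), with 66 genes higher and 32 lower of 12141. These counts were 384 and 185 without control replicate 1, 79 and 112 without control replicate 2, 23 and 14 without liproxstatin replicate 1 and 23 and 5 without liproxstatin replicate 2, and 7 and 2 at resolution 2. Their type I interferon list was lower (-0.32, 29 members, 0 fell, 4 adjusted over the list alone; camera adjusted p = 2.81e-08, and adjusted p = 0.685 with an estimated correlation).

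NK cells had higher Tsc22d3 (1.63 ± 0.12, SE, n = 2 per group), Cebpb (1.24 ± 0.15), Ctla4 (1.01 ± 0.14), Neurl3 (0.85 ± 0.12) and Dusp2 (0.84 ± 0.11), with adjusted p = 0.000123 for Tsc22d3 and 0.0197 for the others by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Cxcl2 (1.08 ± 0.14) rose and Wfdc17 (-1.16 ± 0.16) fell, and both were prone to free RNA. These 7 of 10690 genes compare with 816 at an unadjusted p under 0.05 and with 19 calls in data simulated without change with gene-wise spreads, and 0 with the smoothed trend. They were 6 higher and 1 lower, against 317 and 311 without control replicate 1, 99 and 100 without control replicate 2, 2 and 1 without liproxstatin replicate 1 and 1 and 0 without liproxstatin replicate 2. The integrated stress list was higher (median 0.07, 25 members, of which Cebpb rose, 4 adjusted over the list alone, camera adjusted p = 0.000286, and adjusted p = 0.682 with an estimated correlation). Without control replicate 1 the myeloid suppression, MHC class II and cell cycle lists of NK cells turned direction (camera adjusted p = 0.616, 0.262 and 0.830). In B cells, with 22, 41, 27 and 38 cells, 0 of 3223 genes passed by edgeR, 142 had an unadjusted p under 0.05 and DESeq2 called 0. The count was 17 without control replicate 1, 2 without control replicate 2, 35 without liproxstatin replicate 1 and 127 without liproxstatin replicate 2, 22 with the replicate block and 27 with all classes in 1 fit. With these cells 26% of simulated changes of 4-fold were recovered with gene-wise spreads and 44% with the smoothed trend.

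Across classes the camera test called 65 of 174 combinations of list and class, 40 higher and 25 lower, and 0 with an estimated correlation and 0 by fry (lowest adjusted p = 0.271). In the simulation camera with an estimated correlation also missed the 1 list raised 1.5-fold. That simulation drew genes independently of one another in CD8 T cells only, which favours the preset correlation, and left out fry. It therefore cannot choose between the tests, and the 65 calls stay undecided. The lack of calls by the alternatives cannot show that a list was unchanged. The ferroptosis-promoting, eicosanoid and lymphocyte chemokine lists were called in no class. Ferroptosis defence was higher in mononuclear phagocytes and neutrophil granules likewise, and lipid uptake was higher in mononuclear phagocytes, NK cells and B cells. Oxidative phosphorylation was lower in all classes except B cells. Kept cells had a median mitochondrial share of 2.49% and 2.72% in control and 2.85% and 3.19% in liproxstatin libraries. Their median UMI counts were 16817 and 19462 against 16405 and 15421. Whether such differences in cell quality or depth bear on the oxidative phosphorylation list was not tested. MHC class I was lower in CD8, regulatory and pooled T cells and higher in B cells. T cell exhaustion genes were higher in mononuclear phagocytes, CD8 T cells, pooled T cells and NK cells, and the dissociation list in these 4 classes and dendritic cells. Type I interferon genes were lower in dendritic cells, CD8 T cells and pooled T cells, and the interferon gamma and NF-kappaB lists higher in neutrophils and mononuclear phagocytes. Cytotoxic genes were lower in regulatory T cells and higher in B cells. The B cells had 22 to 41 cells per library, 0 called genes, and free phagocyte RNA at 19.4% of the phagocyte level. Whether RNA of other cells gives the list calls of B cells was not tested. Tsc22d3 rose in neutrophils, mononuclear phagocytes, dendritic cells, CD8 T cells, regulatory T cells and NK cells, which share the same 4 libraries, and did not pass in B cells (log2 fold change 0.45, edgeR adjusted p = 0.999).

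**Figure D3:**
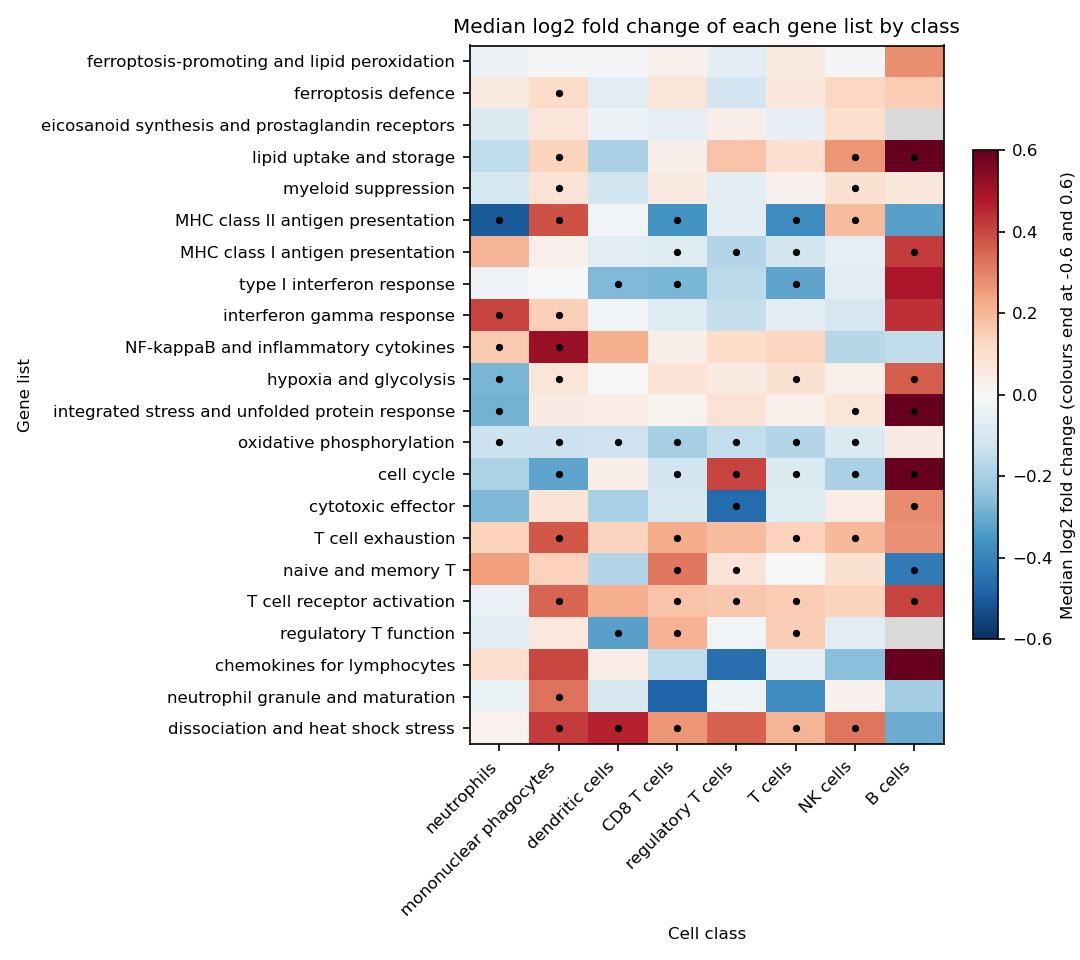
Median log2 fold change of each of the 22 gene lists (vertical axis) in each class (horizontal axis), as colour that saturates at -0.6 and 0.6, with dots on the combinations that camera called and grey where a list was not tested. Cell cycle genes in mononuclear phagocytes lay at -0.32 and interferon gamma genes in neutrophils at 0.41.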

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

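No test in this part was chosen after the result was seen. The response to liproxstatin differed between neutrophils and mononuclear phagocytes for 48 genes by the edgeR quasi-likelihood interaction term with Benjamini-Hochberg adjustment. The log2 fold change was higher in neutrophils for 9 of them and lower for 39. Whether free phagocyte RNA in neutrophils bears on the 39 was not tested. The 8 genes given next were taken because they also passed in neutrophils alone, so they do not represent the 48. Of the genes named in neutrophils, the log2 fold change in neutrophils minus that in mononuclear phagocytes was 1.99 for Rdh11, 1.81 for Icam1, 1.41 for Cxcl10, 1.24 for Gbp5, 1.14 for Rdh12 and 1.12 for Klf3. It was -1.87 for B4galt5 and -1.92 for Pecam1. These 8 genes did not pass without liproxstatin replicate 1 or without liproxstatin replicate 2 (edgeR adjusted p = 1.0 for Icam1 in both), and kept their direction without each library. In simulated data of 5824 genes, against 13546 tested here, the same test gave 28 false calls beside 194 of 200 recovered genes.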

How the results depend on the processing

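Fits of monocytes alone, macrophages alone, equal cells per cluster, without genes prone to free RNA and with named clusters as denominator were chosen after the results were seen. No class share passed under any alternative. The log2 fold change of the neutrophil share moved from 0.35 to 1.26 without control replicate 2 (adjusted p = 0.097 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment) and to -0.19 without control replicate 1. Counts of called genes moved with most settings, and the cause was not tested. Without a control library the spread comes from the liproxstatin pair alone, and without a liproxstatin library from the control pair. The counts in those settings therefore also depend on how alike the remaining pair was. B cells had 22 to 41 cells per library, and 26% of simulated changes of 4-fold were recovered there with gene-wise spreads and 44% with the smoothed trend. At resolution 0.5 regulatory T cells formed no class of their own, and pooled T cells, which contain other classes, did not enter the 1 fit, so neither has a count there.

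Without a filter on low counts, 55 genes were called in neutrophils, 1143 in mononuclear phagocytes, 216 in dendritic cells, 352 in CD8 T cells, 75 in regulatory T cells, 385 in pooled T cells, 201 in NK cells and 38 in B cells. The DESeq2 Wald test called 6 in neutrophils (5 of them higher, 83.3%, against 56.25% by edgeR), 533 in mononuclear phagocytes, 31 in dendritic cells, 68 in CD8 T cells, 7 in regulatory T cells and 24 in NK cells. With doublets kept the counts were 7 in neutrophils, 4 in dendritic cells, 80 in CD8 T cells, 54 in pooled T cells and 2 in B cells. With equal cell numbers, which leaves fewer cells, they were 0 in neutrophils, 17 in CD8 T cells, 9 in regulatory T cells, 32 in pooled T cells, 11 in NK cells and 4 in B cells. With all classes in 1 fit they were 149 in neutrophils (130 higher, 19 lower), 79 in mononuclear phagocytes, 4 in dendritic cells, 41 in CD8 T cells, 6 in regulatory T cells, 2 in NK cells and 27 in B cells, and the median log2 fold change of all neutrophil genes was then 0.18 against -0.02. At least 500 genes per cell gave 10 in neutrophils, under 10% mitochondrial UMIs gave 42 in regulatory T cells, resolution 2 gave 9 in pooled T cells and resolution 0.5 gave 2 in B cells. Equal cells per cluster gave 88 in mononuclear phagocytes, 32 in pooled T cells and 3 in NK cells, and leaving out genes prone to free RNA gave 7 in B cells. Monocytes alone gave 15 genes, with Pdcd1lg2 at -0.012 and Aurka at 0.0734, both against the direction of the pooled phagocytes. Camera with an estimated correlation and fry called 0 lists. Size factors of the DESeq2 kind left every count within 1.5 times.

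With the replicate number as a block, 8 genes were called in neutrophils, 466 in mononuclear phagocytes, 146 in dendritic cells, 473 in CD8 T cells, 99 in regulatory T cells, 233 in pooled T cells, 186 in NK cells, 22 in B cells, and 73 lists. Nothing says that equal numbers share an animal, day or batch. The deviations of libraries with the same number correlated across genes at -0.003 in neutrophils, 0.107 in mononuclear phagocytes, 0.103 in dendritic cells, 0.183 in CD8 T cells, 0.0728 in regulatory T cells, 0.302 in pooled T cells, 0.263 in NK cells and 0.298 in B cells, and with 2 pairs the numbers are not treated as a pairing.

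Leaving out each library in turn, where the lone library of a group is assumed to vary like the other group, gave 7 to 296 genes in neutrophils, 44 to 1029 in mononuclear phagocytes, 3 to 317 in dendritic cells, 25 to 453 in CD8 T cells, 23 to 64 in regulatory T cells, 28 to 569 in pooled T cells, 1 to 628 in NK cells and 2 to 127 in B cells. The interaction gave 2 to 193. Each highest count came without control replicate 1, except in B cells, where it came without liproxstatin replicate 2. Genes that turned direction ranged from -0.4149 to 0.43 for Arg1 in mononuclear phagocytes, from -0.4701 to 3.4055 for Ptgs2 in dendritic cells, from -0.7701 to 2.0276 for Nr4a1 in CD8 T cells, from -0.8953 to 1.0858 for Nr4a1 in regulatory T cells, from -0.8562 to 1.9339 for Nr4a1 in pooled T cells and from -1.4247 to 1.7582 for Havcr2 in NK cells. The difference in H2-Ab1 between neutrophils and phagocytes ranged from -1.6188 to 0.1597. Lists that turned direction had camera adjusted p from 5.27e-07 to 0.438 (MHC class II, neutrophils), 7.41e-07 to 0.6812 (NF-kappaB, neutrophils), 1.32e-07 to 0.488 (hypoxia, neutrophils), 2.15e-11 to 0.6449 (hypoxia, mononuclear phagocytes), 2.23e-39 to 0.2905 (type I interferon, dendritic cells), 0.00012 to 0.7532 (cell cycle, pooled T cells), 3.21e-13 to 0.7265 (T cell receptor activation, pooled T cells), 7.1e-09 to 0.616 (myeloid suppression, NK cells), 3.64e-06 to 0.2621 (MHC class II, NK cells), 4.06e-17 to 0.8301 (cell cycle, NK cells) and 0.019 to 0.869 (hypoxia, B cells). The cause was not tested.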

Other observations

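The gene lists of glucocorticoid-induced, clock, immediate early and heat shock genes, the tests of tissue dissociation and of free RNA for Tsc22d3 and related genes, and the fits of monocytes and macrophages alone were chosen after results were seen. The bound on the spread in the test of MHC class II expression by T cells was also added after its value was seen.

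Monocytes taken alone had higher RNA levels of F3, the gene of tissue factor (log2 fold change 2.14 ± 0.24, SE, n = 2 per group), Cd38 (1.68 ± 0.13), Fkbp5 (1.51 ± 0.18), Klf9 (1.49 ± 0.13) and Tsc22d3 (1.34 ± 0.11), and lower Mmp9, a matrix metalloproteinase gene (-1.61 ± 0.15). Macrophages taken alone had higher Ifnb1 (5.34 ± 0.44), Edn1 (2.12 ± 0.29), Per1 (1.59 ± 0.11) and Tgfb3 (1.30 ± 0.11) and lower Igf1 (-0.83 ± 0.09). By edgeR quasi-likelihood with Benjamini-Hochberg adjustment 11 genes rose and 4 fell in monocytes, and 164 rose and 97 fell in macrophages, with adjusted p = 0.000114 for Cd38 in monocytes and 0.0016 for Igf1 in macrophages. Whether the responses of monocytes and macrophages differ was not tested.

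An unnamed cluster led by Lyve1, Ednrb, Cd209f, Cd209g and Cd163, genes known from tissue-resident macrophages, held 2.28% and 1.94% of immune cells in control and 1.38% and 0.914% in liproxstatin tumours. A cluster led by Ctsk, Mmp9 and Acp5, genes known from osteoclasts, held 0.188% and 0.162% in control and 0.328% and 0.326% in liproxstatin tumours. Neither share was tested. Markers of cells outside the CD45 selection differed between single libraries, with fibroblast markers at 112 CPM and erythroid markers at 93.0 CPM in control replicate 2 against 27.4 and 10.2 CPM in control replicate 1, 39.6 and 10.2 CPM in liproxstatin replicate 1, and 39.9 and 4.57 CPM in liproxstatin replicate 2. Over all kept cells, markers of type 2 innate lymphoid cells, Il5 among them, lay at 32.5 and 21.5 CPM in control and 39.4 and 41.0 CPM in liproxstatin tumours, basophil markers at 16.7 and 14 against 7.26 and 10.6 CPM, and eosinophil markers at 5.08 and 6.88 against 4.05 and 4.42 CPM. These differences were not tested.

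Tsc22d3 rose in 6 classes and did not pass in B cells (0.45, edgeR adjusted p = 0.999), while Klf9 rose in mononuclear phagocytes and CD8 T cells and Per1 and Fkbp5 in mononuclear phagocytes. Free RNA from mononuclear phagocytes as the cause is argued against. It could give a median of only 1.60% of the UMIs of up to 12 genes noticed for this pattern, Tsc22d3 among them, in 5 classes. Free RNA from other cells was not estimated. Glucocorticoid exposure and tissue dissociation may each account for part of the pattern. The median of held-out glucocorticoid-induced genes exceeded the 95th percentile of 10000 random lists in 5 of 6 classes, and was -0.04 in neutrophils. Immediate early and heat shock genes did so in 4 of 6, with medians of -0.14 in neutrophils and -0.39 in regulatory T cells. The random lists ignore correlation between genes and the classes share the same 4 libraries, so these counts are not independent support. Taken singly, 1 held-out gene passed in mononuclear phagocytes and 0 in each other class. In mononuclear phagocytes 14 of the 19 measured held-out genes lay above 0, led by Tnfaip3 (1.29), Cxcr4 (0.74) and Nfkbia (0.74). Sesn1 (-0.39), Angptl4 (-0.25) and Zbtb16 (-0.11) were among those below. The list median cannot tell glucocorticoid exposure from other inputs that raise such genes. Of the 7 immediate early and heat shock genes 0 passed in any class. Another phase of the day stays open, since the arms of the clock differed by -0.48 in mononuclear phagocytes, and handling, stress of the mice and the drug itself are confounded with the groups.

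MHC class II genes were lower in CD8 T cells. Less free RNA from phagocytes could account for it, since 197 other genes prone to free RNA had a median log2 fold change of -0.34 in CD8 T cells, 163 of them below 0. The same genes had a median of 0.04 in mononuclear phagocytes, where the MHC class II list was at 0.38. Expression by the T cells stays open. The 5 members of the list of which free RNA could give at most 25% of the UMIs had a median of 0.14. They were Cd80 (0.55), H2-Oa (0.32), Cd86 (0.14), Ciita (0.03) and H2-DMa (-0.12), none of which passed. Cd80 and Cd86 are costimulatory ligands, and the 5 genes are too few to decide.

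Cell cycle genes were lower in mononuclear phagocytes. A lower share of cells in cycling clusters is a candidate explanation, since with equal cells per cluster in every library the list median moved from -0.32 to -0.0514 and 0 of its 36 members fell. The 3 cycling clusters held 20.6% and 23.6% of these cells in control and 16.1% and 14.2% in liproxstatin tumours. These clusters are defined by the same genes, so the test locates the difference and leaves its origin open, and no biological explanation was tested beyond the treatment groups.

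The libraries can be split 2 against 2 in 3 ways, too few for a share under 0.05. The treatment split called 16 genes in neutrophils, 287 in mononuclear phagocytes, 15 in dendritic cells, 129 in CD8 T cells, 24 in regulatory T cells, 98 in pooled T cells and 7 in NK cells, and the highest of the other splits called 0, 0, 0, 2, 3, 1 and 1. The other splits put 1 control and 1 liproxstatin library in each group. Any difference between control and liproxstatin libraries then widens the spread within groups and can lower the counts. They are therefore no measure of the calls that arise without a treatment difference. In B cells, with 22 to 41 cells per library, the split by replicate number called 45 genes against 0 for the treatment split. What structure of the samples these 45 reflect was not tested.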
